A study of Mus musculus with 8 samples.

How the data were processed

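The series comprised 8 SAGE libraries of microdissected neural tube tissue from FVB mouse embryos of diabetic mothers, 4 of open neural tube and 4 of protrusions. Groups were taken from the source names in the labels, the replicate numbers of the open neural tubes (9, 10, 13 and 14) from their titles, and those of the protrusions (1 to 4) from the order in which the samples are listed. Per the labels' protocols, 7 to 12 ng of total RNA went into each library, which was made with a SOLiD SAGE kit. SAGE reads a short tag next to a restriction site near the 3′ end of each transcript, so a gene's value does not grow with its length, and genes without a usable site are not seen. RNA amounts of this size limit the number of different molecules in a library, and copies made by PCR cannot be told from separate molecules here, so reads are not independent molecules. The files hold whole-number counts per gene symbol, as deposited, with no normalization. The submitters' processing notes name genome build mm9. The mapping program, the rule for assigning tags to genes, the treatment of tags that match several genes and the use of strand are not given in the sources used here. The files give no coordinates, and the reference used for gene names (RefSeq of GRCm38.p6) is of another build, so no coordinates are given.

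The files list 26608 gene symbols, of which 8487 were at 0 in all 8 libraries. Of the 13 mitochondrially encoded genes of the fixed list 0 were matched. Of the 67 genes past the threshold, 58 matched a current symbol of the RefSeq table, 8 a synonym, and 1, LOC100503116, neither. Total counts ranged from 5668054 to 16655583 reads per library. CPM values are the deposited counts scaled to the total of their library, computed here. The level that 3 reads stand for was taken as the floor of each library, and such floors cover counting error only. Library complexity was described by the number of genes with at least 1 read after seeded thinning to the smallest total, by the share of genes of mean 5 to 20 CPM at 0, and by an effective number of tags, the Poisson sample size that would give that share of zeros. The latter was 170964 to 343184 in open neural tube and 667995 to 960720 in protrusions. Its genes were chosen by their mean over all 8 libraries, so a gene silent in a group counts there as missed.

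Differences between groups were tested in R 4.3.3 with edgeR 4.0.16, using filterByExpr with the 2 groups (minimum count 10), TMM factors, robust dispersion and the robust quasi-likelihood F test, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.556, a coefficient of biological variation of 0.746. Standard errors of log2 fold changes were derived from the F statistic. Log2 CPM values used a prior count of 2. Fold changes of genes at 0 in all libraries of a group depend on the prior count, and no fold is given for such genes. Gene lists were tested with limma 3.58.1 camera (preset correlation 0.01) where at least 4 members were tested, adjusted over the 38 lists with enough members out of 40 fixed before the data were examined; the 40 include the sex-linked, mitochondrial and ribosomal lists as signs of sample quality. Distances between and within groups were tested by exact permutation over the 35 splits of the libraries, and the signed spread within groups and library measures over all 70 assignments, the 35 splits and their mirrors. The separated protrusion was described against the attached ones without a test, with the percentile of each list's median among 10000 random lists of the same size matched on mean expression.

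Genes named in the text were chosen by a rule fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among genes past the threshold whose groups do not overlap and whose mean log2 CPM is at least 4. From each list it took up to 4 members past the threshold, or the 2 with the smallest p where none passed, and for lists of other cell types and sample quality also the most abundant member. Some genes that the rule takes are not reported here. Genes named outside this rule are said to be so.

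The scripts were tested on simulated data. For protrusion against open neural tube, with 10210 genes in the step and 50 genes changed at each size, 4% of 2-fold, 54% of 4-fold, 86% of 8-fold and 90% of 16-fold changes were called, and 7 of 124 calls were false. With no change simulated, 0 genes and 0 lists were called. At this number of libraries and this spread, changes of 2-fold are thus seldom called. Simulated genes were drawn independently of each other and without the gap in library complexity between the groups. The simulated false calls therefore do not give the error rates in these data, where splits other than the real one called up to 9 lists.

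The alternatives fixed before the data were examined were relative log expression, upper-quartile and no scaling factors, no low-count filter, a filter of 20 CPM in 4 libraries, DESeq2 1.42.0, limma-voom without and with sample weights, each library left out, protrusions 1 and 2 summed, blood and yolk sac genes removed, thinning to the smallest total, camera with an estimated correlation and fry. Alternatives chosen after seeing the data were genes with a mean of at least 50 CPM, counts scaled down to the effective number of tags, the separated protrusion and open neural tube 13 both left out, and camera with an estimated correlation without the separated protrusion. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.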

Results

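Gene expression was profiled by SAGE, which counts short tags near the 3′ end of transcripts, in neural tube tissue of FVB mouse embryos from diabetic mothers at embryonic day 8.5. The tissue was cut from cryosections by laser. The 4 open neural tube libraries came from normally shaped tissue just anterior to closure site 1, where the neural folds begin to fuse, and the 4 protrusion libraries from outgrowths of the open neural plate. By their labels, protrusion 1 was separated from the neural plate and the other 3 were attached to it. The total count was 10127618 reads in open neural tube 9, 5668054 in open neural tube 10, 16655583 in open neural tube 13 and 8376378 in open neural tube 14. It was 6112477 reads in protrusion 1, 6974253 in protrusion 2, 11430602 in protrusion 3 and 8320255 in protrusion 4. A gene with 3 reads therefore corresponded to 0.180 to 0.529 CPM, and levels below that were treated as not detectable at this depth. This floor takes reads as independent. The effective number of tags was only 170964 to 343184 in open neural tube, so transcripts there could be missed at higher levels too. The labels do not say that the libraries of a group come from separate embryos, and the titles of protrusions 1 and 2 share a stem, so p-values measure the spread between these libraries, which may be partly technical and would be too small if libraries share an embryo.

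Fewer genes were detected in every open neural tube library than in any protrusion library. With all libraries thinned to 5668054 reads, 10536 ± 708 genes (SD, n = 4) had at least 1 read in open neural tube and 14776 ± 497 (SD, n = 4) in protrusions (exact permutation test, 2-sided p = 0.0286, the smallest that 4 against 4 libraries allow). Among 3280 genes with a mean of 5 to 20 CPM, 4.85% to 18.8% were at 0 in the open neural tube libraries and 0.0915% to 0.549% in the protrusions. This difference ran along with the groups in every comparison of protrusions with open neural tube. Of the 36 genes that fell, 31 had a mean of at least 100 CPM, a range in which 0.0132% of the open neural tube values were at 0. Of the 31 genes that rose, 15 did, while 6 had a mean of 5 to 20 CPM and 1 a mean under 5 CPM, ranges in which 11.1% and 40.3% of the open neural tube values were at 0.

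**Figure D1:**
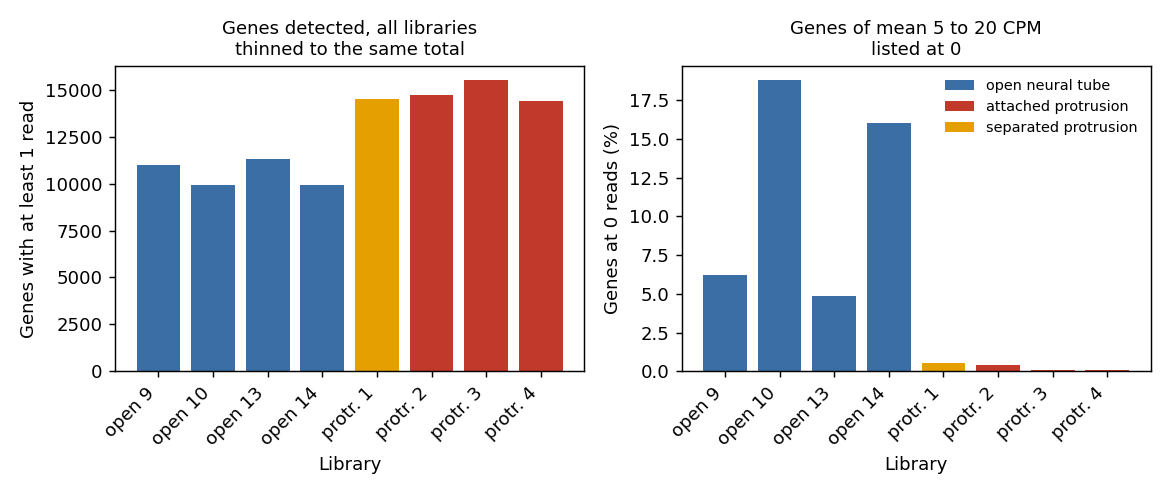
Left, genes with at least 1 read in each library after thinning to the same total (bars, number of genes); right, share of the 3280 genes of mean 5 to 20 CPM that are listed at 0 in each library (bars, percent). The 4 open neural tube libraries lie between 9920 and 11286 genes and the 4 protrusion libraries between 14399 and 15498.

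The main comparison asked which genes differ between protrusions and the normally shaped open neural plate. Protrusions carried transcripts of posterior and gastrulating tissue that were nearly undetectable in open neural tube. The source names place the open neural tubes at the anterior boundary of closure site 1 and give no axial level for the protrusions. A difference in axial position therefore cannot be told apart from the protrusion itself. Cdx2, a caudal homeobox gene of the posterior embryo, stood at 211 ± 87.9 CPM (SD, n = 4) in protrusions and 1.96 ± 1.67 CPM (SD, n = 4) in open neural tube. Tbx6, which directs cells of the primitive streak into paraxial mesoderm, stood at 188 ± 123 CPM against 0.583 ± 0.555 CPM (SD, n = 4 each), and the posterior Hox gene Hoxb9 at 383 ± 375 CPM against 0.543 ± 0.296 CPM (SD, n = 4 each). Falls past the threshold were smaller and concerned abundant transcripts. Among them were Fzd7, a Wnt receptor, at 268 ± 100 CPM in protrusions against 1032 ± 287 CPM in open neural tube, and Sox11, a transcription factor of neural progenitors, at 1014 ± 276 CPM against 2352 ± 415 CPM (SD, n = 4 each, Sox11 chosen after its values were seen). With the separated protrusion left out, larger falls passed as well, such as Dbx1 at −8.59 and Zic1 at −7.66 on the log2 scale (chosen after their values were seen).

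Of 11036 genes tested with edgeR's quasi-likelihood test, 67 passed a Benjamini-Hochberg adjusted p of 0.05, 31 higher and 36 lower in protrusions. In all 67 the 4 protrusion values lay on the same side of the 4 open neural tube values, a separation seen in 13.2% of the tested genes and in 2.86% by chance. The median log2 fold change was 4.06 among the genes that rose and −1.23 among those that fell. An unadjusted p under 0.05 was found for 1694 genes, where 551.8 are expected by chance. Nodal, a signal of gastrulation, had 0 reads in all 4 open neural tubes and 23.0 ± 14.9 CPM in protrusions (SD, n = 4). Polr2a, the largest subunit of RNA polymerase II, which every cell uses, was likewise at 0 in all 4 open neural tubes, at 0.65 CPM in the separated protrusion and at 7.57 to 24.1 CPM in the attached ones, so 0 reads do not show that a transcript was absent from open neural tube (Nodal and Polr2a were chosen after their values were seen). Leaving out open neural tube 9, 10, 13 or 14 gave 1, 8, 52 or 2 genes past the threshold. Of these, 1, 7, 26 or 2 were among the 67. Leaving out protrusion 2, 3 or 4 gave 19, 22 or 6 genes, with 17, 19 or 6 of the 67 among them. Leaving out the separated protrusion 1 gave 172, with 64 of the 67 among them. With the separated protrusion and open neural tube 13 both left out, a setting chosen after seeing the data, 211 genes passed, 115 higher and 96 lower. Of the 67 genes, 50 were among them.

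Among genes with a mean log2 CPM of at least 4, the largest rise was that of 2700086A05Rik, the long noncoding RNA Hoxaas3 of the Hoxa cluster, by 7.33 ± 0.90 (log2 fold change ± SE; edgeR adjusted p = 0.0111). Its call ended with limma-voom, without and with sample weights, and without open neural tube 9, 10 or 14 or protrusion 4 (adjusted p up to 0.179). It is antisense to Hoxa genes, and whether tags were assigned by strand is not given in the sources used here. Next came Cdx2 (6.56 ± 0.64, adjusted p = 0.00582) and Cdx1 (4.06 ± 0.67, adjusted p = 0.0390), both of the caudal family. Rftn1, a lipid raft protein, rose by 3.75 ± 0.68, Gbx2, a homeobox gene of the anterior hindbrain and of the gastrulating embryo, by 3.31 ± 0.40, and Zyx, a focal adhesion protein, by 2.73 ± 0.51. Grsf1, an RNA-binding protein, rose by 2.69 ± 0.48, Sema6a, a transmembrane semaphorin, by 2.68 ± 0.49, and the transcription factor Arid3b by 2.50 ± 0.32. Snrnp25, a spliceosomal protein, rose by 2.26 ± 0.38, the lysosomal membrane protein Laptm4b by 1.90 ± 0.32, and LOC100503116, a symbol without a match in the current gene table, by 1.71 ± 0.29. Their adjusted p-values in edgeR lay between 0.0111 and 0.0477. Each gene past the threshold that the fixed rule took lost its call in 1 to 10 of 19 to 22 alternatives.

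The largest falls in the same abundance range were those of Cxcr7 (now Ackr3), a scavenging chemokine receptor, by −2.57 ± 0.46 on the log2 scale (edgeR adjusted p = 0.0450), and Fzd7, by −2.03 ± 0.30 (adjusted p = 0.0261). Arf6, a small GTPase of membrane traffic, fell with −1.95 ± 0.32, Slc25a37, the mitochondrial iron importer, with −1.60 ± 0.29, and Evi5, a regulator of cell division, with −1.57 ± 0.22. Zfp462, a zinc finger protein, fell with −1.55 ± 0.28, Ampd2, an AMP deaminase, with −1.54 ± 0.17, and the mitochondrial lipid transfer protein Prelid1 with −1.52 ± 0.23. AI314180 (now Ecpas), a proteasome adaptor, fell with −1.49 ± 0.26, Psma2, a proteasome subunit, with −1.45 ± 0.18, Vezf1, a zinc finger transcription factor, with −1.32 ± 0.17, and the Mediator subunit Med10 with −1.32 ± 0.22. Their adjusted p-values in edgeR lay between 0.00979 and 0.0450.

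**Figure D2:**
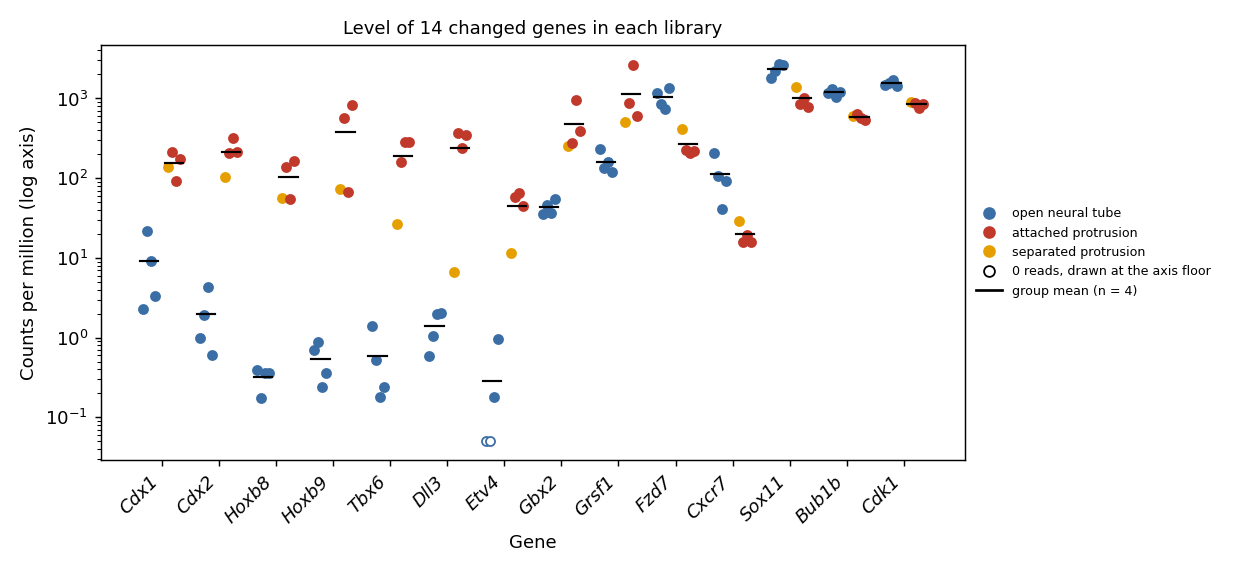
CPM (log axis) of 14 genes past the threshold in each of the 8 libraries; points are libraries, coloured by morphology, lines are group means (n = 4 each), and open points are 0 reads drawn at the axis floor. Hoxb9 lies between 66.7 and 819 CPM in protrusions and at most at 0.882 CPM in open neural tube, and the separated protrusion lies below the attached ones for Tbx6, Dll3 and Etv4.

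Genes of the primitive streak and of axial progenitors were higher in protrusions as a group. Of 21 members fixed before the data were examined, 11 could be tested and 10 had a fitted fold change above 0, with a median log2 fold change of 4.34. Cdx2, Cdx1 and Grsf1 rose over all genes tested, and 10 members rose when adjusted over the list alone. T, the Brachyury gene of the streak and notochord, stood at 413 ± 292 CPM in protrusions and 5.97 ± 7.85 CPM in open neural tube (SD, n = 4 each; log2 6.15 ± 1.32, edgeR adjusted p = 0.0698). The list was called higher by camera with a preset correlation of 0.01 (adjusted p = 6.44e-08), and the call was lost at adjusted p = 0.243 with an estimated correlation.

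The posterior Hox genes showed the highest median of all lists. Of the 20 genes of Hox paralog groups 6 to 13, 4 were tested, with a median log2 fold change of 7.04. Their median level was only −1.15 to 0.28 log2 CPM in the open neural tube libraries. With such levels, members passed the low-count filter through their reads in protrusions, so a high median is partly set by the filter. Hoxb8 rose by 8.13 ± 0.60 (edgeR adjusted p = 0.000809) and Hoxb9 passed as well (adjusted p = 0.0111), and 3 of the 4 rose when adjusted over the list alone. The call of Hoxb8 ended with sample weights (adjusted p = 0.125). That of Hoxb9 ended with limma-voom, without and with sample weights, when scaled to effective tags, and without open neural tube 9, 10 or 14 (adjusted p up to 0.354). Hoxb8 stood at 103 ± 56.5 CPM in protrusions and 0.322 ± 0.0988 CPM in open neural tube (SD, n = 4 each). The latter lies in the range that 3 reads stand for, and at the complexity of these libraries transcripts can be missed at higher levels too. Camera called the list (adjusted p = 5.46e-05), with adjusted p = 0.243 with an estimated correlation, and the call ended with limma-voom. Of the anterior Hox genes, paralog groups 1 to 5, 13 were tested and 0 passed, over all genes or adjusted over the list alone (camera adjusted p = 0.617, median 0.51). Hoxc4 had a log2 fold change of 4.22 ± 1.43 (edgeR adjusted p = 0.181) and Hoxb1 of 3.53 ± 1.23 (adjusted p = 0.193).

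Targets of FGF signalling and of Wnt/β-catenin signalling were also higher in protrusions. Of 14 tested FGF/ERK targets, 13 had a fitted fold change above 0, with a median log2 fold change of 2.64. Etv4, an ETS factor induced by FGF, rose by 7.14 ± 1.09 (edgeR adjusted p = 0.0300), from 0.284 ± 0.455 CPM in open neural tube to 44.7 ± 23.6 CPM in protrusions (SD, n = 4 each), and 9 members rose when adjusted over the list alone. Of 15 tested Wnt targets, 12 had a fitted fold change above 0 (median 1.30), Cdx1 rose over all genes, and 8 members rose when adjusted over the list alone. The Wnt list as fixed shares Cdx1, T and Sp5 with the primitive streak list, so its call is not separate from the call of that list. The FGF list was called by camera (adjusted p = 8.84e-07), with adjusted p = 0.243 with an estimated correlation. The Wnt list was called with adjusted p = 0.00323, and with adjusted p = 0.246 with an estimated correlation.

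Within the paraxial mesoderm and somite list, Tbx6 rose by 8.22 ± 0.93 (edgeR adjusted p = 0.0111) and Dll3, a Notch ligand of presomitic mesoderm, by 7.28 ± 1.09 (adjusted p = 0.0265). The call of Tbx6 ended under the same settings as that of Hoxb9, and that of Dll3 in 10 of 20 alternatives, among them limma-voom, no low-count filter and each library left out except protrusion 1 (adjusted p up to 0.439). Of 16 tested members, 2 rose over all genes, 5 rose when adjusted over the list alone, and the median log2 fold change was 1.22. The most abundant member, Aldh1a2, stood at 258 ± 220 CPM in protrusions and 90.5 ± 110 CPM in open neural tube (SD, n = 4 each). Camera called the list higher (adjusted p = 0.0388), with adjusted p = 0.612 with an estimated correlation. The call also ended without open neural tube 9, 10 or 14, without protrusion 1, 3 or 4, with no scaling factor, with no low-count filter and with limma-voom.

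Dll3 was also the member of the Notch pathway list that rose, and 3 of its 11 tested members rose when adjusted over the list alone (median 0.97, camera adjusted p = 0.104). Gbx2 was the member of the fore-, mid- and hindbrain list that rose, over all genes and adjusted over the list alone, of 4 tested (median −1.80, camera adjusted p = 0.915). Pmaip1, a pro-apoptotic target of p53, rose by 5.41 ± 0.95 (edgeR adjusted p = 0.0438). Of 17 tested p53 targets it was the only member past the threshold over all genes, and 2 rose when adjusted over the list alone (median 0.04, camera adjusted p = 0.538). In the pluripotency and epiblast list 0 of 6 tested members passed over all genes and 3 rose when adjusted over the list alone (median 1.92, camera adjusted p = 0.0988). Dnmt3b had a log2 fold change of 1.71 ± 0.50 (edgeR adjusted p = 0.118) and Sall4 of 3.17 ± 0.96 (adjusted p = 0.133). Lin28a, the most abundant, stood at 2217 ± 482 CPM against 2058 ± 344 CPM (SD, n = 4 each).

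Mitotic genes fell in 2 of 22 tested members. Bub1b, a spindle checkpoint kinase, fell with −1.10 ± 0.15 on the log2 scale (edgeR adjusted p = 0.0141), and Cdk1, the mitotic cyclin-dependent kinase, with −0.95 ± 0.15 (adjusted p = 0.0385); 4 members fell when adjusted over the list alone. The list as a whole was not called (camera adjusted p = 0.104, towards lower, against a median of 0.06 and a mean of −0.05). Of 20 S-phase genes 0 passed over all genes, 2 rose and 3 fell when adjusted over the list alone, and Cdt1, a replication licensing factor, had a log2 fold change of −0.90 ± 0.22 (edgeR adjusted p = 0.0820; camera adjusted p = 0.381, median −0.07).

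Neural identity genes passed no list test in this comparison of all 8 libraries; without the separated protrusion, camera with the preset correlation called the dorsoventral patterning and neural progenitor lists lower (adjusted p = 0.00270 and 0.0203; 0.540 and 0.666 with an estimated correlation). Of 16 tested neural progenitor genes 0 passed, over all genes or adjusted over the list alone (median −0.36, camera adjusted p = 0.257). Ncam1 had a log2 fold change of 1.02 ± 0.37 (edgeR adjusted p = 0.214) and Sox3 of 4.01 ± 1.48 (adjusted p = 0.219). Of 10 dorsoventral patterning genes 0 passed by either adjustment (median −1.73, camera adjusted p = 0.0636). Dbx1, a gene of intermediate neural tube progenitors, stood at 7.14 ± 13.6 CPM in protrusions and 128 ± 119 CPM in open neural tube (SD, n = 4 each; adjusted p = 0.245), and Olig3 had a log2 fold change of 4.03 ± 1.74 (adjusted p = 0.301). Of 9 neuronal differentiation genes 0 passed by either adjustment (median 0.55, camera adjusted p = 0.445), with Gap43 at 2.54 ± 0.86 (adjusted p = 0.180) and Tubb3 at 1.46 ± 0.94 (adjusted p = 0.523). Of 27 tested genes needed for neural tube closure 0 passed over all genes, and 2 rose and 1 fell when adjusted over the list alone (median 0.14, camera adjusted p = 0.978). Cited2 had a log2 fold change of 1.82 ± 0.43 (adjusted p = 0.0794) and Sfrp1, a secreted Wnt inhibitor, of −2.51 ± 0.60 (adjusted p = 0.0812).

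Endothelial genes were lower in protrusions as a list, with no member past the threshold over all genes or adjusted over the list alone. All 8 tested members had a fitted fold change below 0, with a median of −1.92 (camera adjusted p = 0.0282), and adjusted p = 0.661 with an estimated correlation. Sox18 had a log2 fold change of −2.01 ± 0.92 (edgeR adjusted p = 0.337), Sox7 of −2.79 ± 1.45 (adjusted p = 0.406), and Egfl7, the most abundant, stood at 51.3 ± 24.8 CPM against 82.6 ± 44.4 CPM in open neural tube (SD, n = 4 each). Sox7 was highest in open neural tube 13, at 142 CPM, and without that library the list was no longer called, nor was it by fry (adjusted p = 0.317).

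The lateral plate, mesenchyme and cardiac lists did not pass the test. Open neural tube 13 stood apart from the other open neural tubes in several of their members, with Pdgfra, a growth factor receptor of mesenchyme, at 475 CPM against 29.9 to 66.0 CPM. Of 4 lateral plate, 14 mesenchyme and 7 cardiac genes tested, 0 passed by either adjustment (camera adjusted p = 0.898, 0.983 and 0.0792; medians −0.76, −0.31 and 0.29). Twist1, a mesenchymal transcription factor, had a log2 fold change of −1.90 ± 0.95 (edgeR adjusted p = 0.380), Myl4 of 3.43 ± 1.60 (adjusted p = 0.342) and Acta2 of 3.28 ± 1.58 (adjusted p = 0.361). Pdgfra, the most abundant of the lateral plate and mesenchyme lists, stood at 112 ± 42.3 CPM in protrusions and 151 ± 217 CPM in open neural tube, and Acta2, the most abundant cardiac gene, at 20.6 ± 21.4 CPM and 1.92 ± 3.61 CPM (SD, n = 4 each). Of 19 genes of epithelial-mesenchymal transition 0 passed by either adjustment (median −0.38, camera adjusted p = 0.0988), with Twist2 at −3.44 ± 1.10 (adjusted p = 0.154) and Zeb2 at −0.91 ± 0.31 (adjusted p = 0.175).

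The remaining lists of other cell types were not called. Of 9 neural crest genes 0 passed by either adjustment (median −1.76, camera adjusted p = 0.0629). Crabp1, the most abundant, stood at 1795 ± 2301 CPM in protrusions and 8403 ± 6616 CPM in open neural tube (SD, n = 4 each; edgeR adjusted p = 0.250), and Ednrb had a log2 fold change of −3.42 ± 1.31 (adjusted p = 0.234). Of 11 surface ectoderm genes 1, Cdh1, rose when adjusted over the list alone (median 0.70, camera adjusted p = 0.456). Cdh1, an epithelial cadherin and the most abundant, stood at 270 ± 400 CPM against 24.7 ± 12.6 CPM (adjusted p = 0.0895), and Krt18 had a log2 fold change of −1.03 ± 0.64 (adjusted p = 0.510). Of 9 notochord and floor plate genes 1, T, rose when adjusted over the list alone (median 0.74, camera adjusted p = 0.555), and Sox9 had a log2 fold change of −0.58 ± 0.41 (adjusted p = 0.568). Of 9 gut endoderm genes 0 passed (median 0.50, camera adjusted p = 0.724), with Spink3 at −4.22 ± 1.32 (adjusted p = 0.148) and Tmprss2 at 3.22 ± 1.23 (adjusted p = 0.233), and Foxa2, the most abundant, at 19.1 ± 12.3 CPM and 12.8 ± 3.85 CPM.

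The blood and yolk sac lists were not called. Of 6 primitive erythroid genes 0 passed (median −0.09, camera adjusted p = 0.799). Hba-x, an embryonic globin and the most abundant, stood at 11.8 ± 22.1 CPM in protrusions and 487 ± 528 CPM in open neural tube (SD, n = 4 each; edgeR adjusted p = 0.201), and Cpox had a log2 fold change of 0.50 ± 0.42 (adjusted p = 0.649). Of 5 yolk sac endoderm genes 0 passed (median −0.48, camera adjusted p = 0.426), with Mttp at −0.90 ± 0.63 (adjusted p = 0.572) and Apoe, the most abundant, at 129 ± 70.3 CPM and 84.4 ± 28.5 CPM. Of the myeloid list only Coro1a was tested (1.40 ± 1.21, adjusted p = 0.661), at 9.47 ± 6.06 CPM and 3.24 ± 3.19 CPM. The sex-linked list was not called (5 tested, median 0.32, camera adjusted p = 0.983), with Kdm5d at 2.36 ± 2.02 (adjusted p = 0.656), Uty at −0.82 ± 1.24 (adjusted p = 0.827) and Ddx3y, the most abundant, at 105 ± 77.8 CPM and 181 ± 124 CPM. This list joins Xist with Y-linked genes, which go opposite ways with sex, so a directional test of it cannot show a difference in sex.

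Of the metabolic and stress lists, camera with the preset correlation called the nuclear genes of oxidative phosphorylation, towards lower in protrusions. Of 22 tested, 7 had a fitted fold change above 0, the median was −0.24, 0 passed over all genes, and 1 rose and 5 fell when adjusted over the list alone. Ndufa1 had a log2 fold change of −0.97 ± 0.25 and Sdhd of 0.82 ± 0.21 (edgeR adjusted p = 0.0832 for both). The camera call (adjusted p = 0.0115) was lost at adjusted p = 0.243 with an estimated correlation. It also ended among genes with at least 20 CPM in 4 libraries, at a mean of at least 50 CPM and when scaled to effective tags (adjusted p up to 0.581). The list is abundant, with a mean log2 CPM of 8.26 in open neural tube and 8.12 in protrusions. All tested genes with a mean of at least 100 CPM had a median log2 fold change of −0.13, and those under 5 CPM of 0.44. Camera compares a list with all other genes, so this call cannot be told apart from that trend with abundance. Glycolysis and glucose uptake genes were not called (17 tested, median 0.57, camera adjusted p = 0.501), with 1 rising when adjusted over the list alone. Slc2a3, a glucose transporter, had a log2 fold change of 1.86 ± 0.42 (adjusted p = 0.0740) and Pfkm of 1.70 ± 0.50 (adjusted p = 0.122). Oxidative stress genes were not called (17 tested, median −0.11, camera adjusted p = 0.501), with 1 falling when adjusted over the list alone; Sod1, a superoxide dismutase, had −1.38 ± 0.30 (adjusted p = 0.0709) and Gclm 2.47 ± 1.04 (adjusted p = 0.286).

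Hypoxia genes were not called (15 tested, median −0.53, camera adjusted p = 0.456), with 3 rising and 2 falling when adjusted over the list alone. Kdm3a stood at 135 ± 25.6 CPM in protrusions and 54.8 ± 14.7 CPM in open neural tube (SD, n = 4 each; edgeR adjusted p = 0.0584), and Egln1 had a log2 fold change of −0.96 ± 0.24 (adjusted p = 0.0832). Of 17 unfolded protein response genes 1 fell when adjusted over the list alone (median 0.01, camera adjusted p = 0.898), with Hsp90b1 at −0.61 ± 0.15 (adjusted p = 0.0832) and Hspa5 at −0.55 ± 0.19 (adjusted p = 0.175). The epithelial junction list (21 tested, median 0.11, camera adjusted p = 0.943) had 2 members rising when adjusted over the list alone, among them Cdh1. The hedgehog list (12 tested, median 0.04, camera adjusted p = 0.115) had 1 falling, Gli2 (−0.90 ± 0.21, adjusted p = 0.0794), beside Cdon (−1.14 ± 0.44, adjusted p = 0.242). The retinoic acid list (12 tested, median 0.96, camera adjusted p = 0.538) had 3 rising and 1 falling; Rarb, a retinoic acid receptor, had −3.03 ± 0.72 (adjusted p = 0.0794). The BMP list (10 tested, median 0.07, camera adjusted p = 0.983) had 0, with Id3 at −1.01 ± 0.53 (adjusted p = 0.408) and Msx2 at −2.37 ± 1.67 (adjusted p = 0.570).

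Ribosomal protein genes were not called (27 tested, median 0.06, camera adjusted p = 0.900). Over all genes 1 member rose, 4 members rose and 1 fell when adjusted over the list alone, and Rpl8, the most abundant, stood at 7888 ± 471 CPM and 5729 ± 1393 CPM (SD, n = 4 each). Of the 48 ribosomal genes 19 were listed at 0 in all 8 libraries, and tags of this family can be shared with near-identical copies, so these values are uncertain. In 9 lists the median, the mean and the camera direction differed in sign, namely mesenchyme, neural tube closure, hedgehog, BMP, oxidative stress, unfolded protein response, S phase, mitosis and ribosomal protein. Over all 8 libraries, camera with the preset correlation called 7 of the 38 lists tested, fry, a directional test, called 10, and with an estimated correlation 0 passed an adjusted p of 0.05 (smallest 0.243). Without the separated protrusion, camera called 9 with the preset correlation and 2 with an estimated one, the latter a combination chosen after seeing the data.

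**Figure D3:**
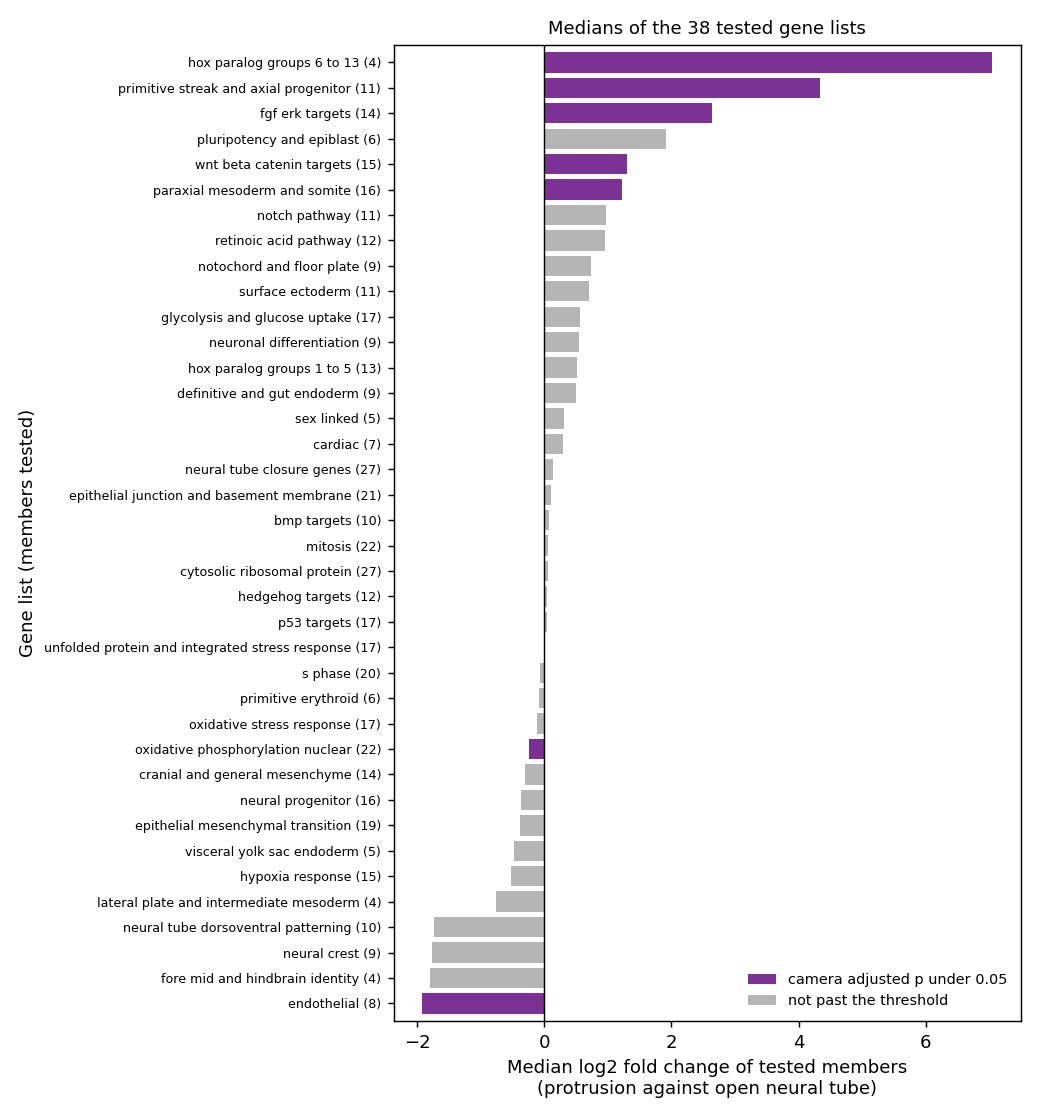
Median log2 fold change (protrusion against open neural tube) of the tested members of 38 gene lists fixed before the data were examined, with the number tested in brackets; purple bars are the 7 lists called by camera with the preset correlation. The posterior Hox list has the highest median, 7.04, and the endothelial list the lowest, −1.92.

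Protrusion libraries resembled each other more than they resembled open neural tube libraries, while open neural tube libraries were nearly as far from each other as from protrusions. Over the 500 most variable genes the mean distance was 2.12 log2 units within protrusions, 3.98 within open neural tube and 4.42 between groups. The mean distance between groups exceeded the mean distance within groups by 1.37 log2 units (exact permutation test over 35 splits, 1-sided p = 0.0286, the smallest possible). In library similarity this excess was 0.69 with at least 20 CPM in 4 libraries and 0.56 when scaled to effective tags (exact permutation p = 0.0571 each), and 0.69 at a mean of at least 50 CPM (exact p = 0.0286). Without protrusion 1, 2, 3 or 4 it was 1.73, 0.80, 0.86 or 0.82 in library similarity (exact permutation p = 0.0571, 0.0571, 0.0571 and 0.0857). The first principal component held 53.6% of the variance and placed the attached protrusions at 45.8 to 50.9 and open neural tubes 9, 10 and 14 at −58.4 to −40.0. The separated protrusion lay at 4.99 and open neural tube 13 at −0.02. Spearman correlations across genes had a mean of 0.919 within protrusions (0.870 to 0.965), 0.844 within open neural tube (0.813 to 0.875) and 0.842 between groups (0.785 to 0.920). The highest between groups, 0.920, was that of open neural tube 9 with the separated protrusion, above every pair of open neural tubes and every other pair with the separated protrusion.

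Over all tested genes, open neural tube libraries varied more among themselves than protrusions, by an amount that depended on the filter and scaling. The median standard deviation over genes was 0.844 log2 units in open neural tube and 0.413 in protrusions, a difference of −0.43 (protrusion minus open; exact permutation test, 2-sided p = 0.0286, n = 4 each). Without the low-count filter, the spread within each group differed by −0.046 (p = 0.743, exact permutation test), and at a mean of at least 50 CPM by −0.10 (exact p = 0.114). It differed by −0.18 with at least 20 CPM in 4 libraries and by −0.15 when scaled to effective tags (exact permutation p = 0.0286 each). Without open neural tube 9, 10, 13 or 14 the difference was −0.36, −0.25, −0.31 or −0.35 (exact permutation p = 0.200, 0.143, 0.286 and 0.143). Among tested genes with a mean under 5 CPM, 40.3% of the open neural tube values and 1.04% of the protrusion values were at 0.

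The separated protrusion differed from the attached ones in several lists, in both directions. Cdx1 stood at 138 CPM and Cdx2 at 105 CPM in it, against 91.9 to 211 and 207 to 320 CPM in the attached protrusions, whereas T stood at 36.8 against 379 to 737 CPM, Dll3 at 6.71 against 241 to 369 CPM, and Sox3 at 0 against 23.9 to 50.7 CPM. Hoxb8 stood at 55.6 and Hoxb9 at 74.1 CPM, within the range of the attached protrusions, 54.2 to 164 and 66.7 to 819 CPM (these genes were picked after their values were seen). The median of the primitive streak list differed from the attached protrusions by −1.10 log2 units (percentile 0.34 among 10000 random lists matched on expression), that of FGF targets was at −1.31, of the Notch list at −1.40 and of the notochord list at −3.07. That of the anterior Hox list, paralog groups 1 to 5, was at −1.32 (percentile 0.01), with a median level of 2.97 against 4.25 to 6.03. The median of the dorsoventral patterning list was 3.18 log2 units above the attached protrusions (percentile 100). The neural progenitor list stood at a median log2 CPM of 6.22 against 4.75 to 5.38 in the attached protrusions, and the endothelial list at 3.14 against −0.15 to 0.41, also at percentile 100. The members of the neural crest, mesenchyme, lateral plate, paraxial and retinoic acid lists had median differences of 1.26, 1.09, 1.01, 0.75 and 0.57 log2 units (percentiles of 99.7 to 100), although the median levels of the paraxial and retinoic acid lists, 4.71 and 5.45, were below those of the attached protrusions, 5.68 to 6.53 and 5.59 to 6.61. Lists of general functions differed too, with the unfolded protein response list at a median level of 4.08 against 5.34 to 5.53 and the glycolysis list at 7.59 against 8.14 to 8.54 (median differences of members −0.34 and −0.69, percentiles 4.25 and 0). The ribosomal protein list stood at 8.48 against 10.05 to 10.33, although the median difference of its members was 0.17 (percentile 58.9). With 1 separated library there is no test, and these values describe this library alone.

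Of the genes called between attached protrusions and open neural tube without the separated library, 80 higher ones could be evaluated in it. Its median position on the log2 scale was 0.39 of the way from the open neural tube mean to the attached mean for higher genes and 0.52 for 85 lower ones. It lay above all 4 open neural tube libraries in 47 of the 80 (58.8%) and below them in 68 of the 85. On the same scale, log2 CPM with TMM factors, it lay on the other side of all 4, below them, in 18 of the 80 higher genes (22.5%). Among them were the translation factor Eif5a and the tRNA ligase Vars (chosen after their values were seen).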

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

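Tests chosen only after the result was seen were those of sequencing depth, of the uniform mixture and its implied shares, of library complexity, of the separated protrusion as an open neural tube, of carry-over, and of open neural tube 13 as a protrusion on genes higher in protrusions. Of 188 gene values and 76 list values examined per group, 25 and 8 had a library far from the other 3 of its group, with a gap to the nearest above Dixon's 95% critical value, which chance gives in about 1 of 20 groups. Of 10 library measures 0 did. All values are log2 CPM.

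In protrusion 1, the separated library, Cxcr7 was at 4.86, AI314180 at 5.79, Ednrb at 2.20, Sox7 at 5.06 and Egfl7 at 6.46, above the attached protrusions, and Sox3 at −2.20, Dll3 at 2.78 and Etv4 at 3.54, below them. Its endothelial list median was 3.14, its unfolded protein response median 4.08 and its ribosomal protein median 8.48. In open neural tube 13, Krt18 was at 7.70, Hspa5 at 10.67 and Kdm5d at 2.52, above the other open neural tubes, and Tubb3 at −1.53, below them. Its neural progenitor median was 3.92, its neuronal differentiation median −1.53 and its cardiac median 3.51. In open neural tube 10, Rftn1 was at −0.82, Hoxb8 at −1.35, Sall4 at 0.33, and Uty and Ddx3y at 0.12. In open neural tube 9, Olig3 was at 2.27 and the ribosomal protein median at 8.58. In protrusion 2, Hsp90b1 was at 10.20 and the mesenchyme median at 2.94. In protrusion 3, LOC100503116 was at 8.50, Cdh1 at 9.59, Uty at −1.15 and Ddx3y at −0.72, and in protrusion 4 Egln1 was at 7.51.

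Fewer genes were detected in the open neural tube libraries. Lower depth is argued against by a gap of 3113 genes between the lowest protrusion and the highest open neural tube after thinning. A biological explanation, genes not transcribed in open neural tube, was tested by the share at 0 in all 4 libraries. Of 1445 genes missed by at least 1 open neural tube, 2.70% were at 0 in all 4 (95% exact binomial interval 1.93 to 3.67%). This argues against genes without any read there as the main cause. However, 1 read in any of the 4 libraries counted as detection. Kif26b, chosen after its values were seen, had 1 read in open neural tube 13, 0 in the others and 19.9 ± 9.36 CPM in protrusions (SD, n = 4), and counted as detected. Genes with only a few reads in open neural tube are thus not settled by this test. Fewer independent tags captured from these tissues stays a candidate explanation. Of 594 genes at 10 to 50 CPM in the protrusions and at 0 in at least 1 open neural tube, 98.7% were detected in another (97.4 to 99.4%). This share is nearly the complement of the 2.70% above, over overlapping genes, so it adds no separate evidence. Lower but not absent transcription, or differences among the open neural tubes, would give such a share too, so this test cannot tell them apart. Why fewer tags would be captured stays open.

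The separated protrusion lay between open neural tube and the attached protrusions on the first principal component, and lower library complexity is argued against by its 14505 genes after thinning, next to 14399 in the lowest attached protrusion and 11286 in the highest open neural tube. As for a mislabelled open neural tube, the separated library exceeded all 4 open neural tubes in 58.8% of 80 genes called higher without it (47.2 to 69.6%). These genes were called because those 4 libraries were low in them, and the interval treats genes of 1 library as independent. The share that a true open neural tube would give is thus not known, and this test does not settle the question. A uniform mixture of attached-type and open tissue needs 1 share of attached-type tissue, and the genes implied medians of 0.121 over 80 higher and 0.739 over 85 lower ones. It still cannot be told apart from a different state, since this gap was 0.580 on genes called without a pair of left-out libraries and 0.251 to 0.676 in mixtures computed from those pairs, which could be had with open neural tube 13 alone, and since the interquartile range of its ratio to the other protrusions, 2.04 log2 units over 80 genes, was set against 0.68 to 1.61 over only 5 to 16 genes for the attached ones. Separation from the neural plate, which the labels give, stays open and untested with 1 library.

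Open neural tube 13 carried mesodermal transcripts, with the paraxial list 2.18, the lateral plate list 3.67 and the mesenchyme list 3.14 log2 units above the other open neural tubes. Low library complexity is argued against, as its 11286 genes after thinning were the most of the 4. As for a mislabelled protrusion, it lay below all 4 protrusions in 83.8% of 37 genes called higher in protrusions without it (68.0 to 93.8%). These genes were called because those 4 protrusions were high in them, so the share that a true protrusion would give is not known. Over all 52 genes called without it, 50% lay nearer to the protrusion mean (35.8 to 64.2%). Neither test settles the question. Carry-over of adjacent mesoderm stays open, since the neural progenitor list stood at −2.16 (95% interval of the median −3.57 to −1.09), more than a carried-over share below 50% would dilute it, and a larger share cannot be told apart from another neural state. No biological explanation was tested.

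Among the 35 splits of the 8 libraries into groups of 4, only the real split gave 67 genes, and the highest other gave 17, with open neural tube 13 in place of the separated protrusion. Being 1 of 35 is the smallest share this design allows, so chance is made unlikely for the count of genes but is not excluded. The gap in library complexity follows the real split too, and this test does not separate it from the tissue. For the 7 lists, 6 of the 35 splits gave as many, the highest other 9, so chance is not excluded.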

How the results depend on the processing

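Alternatives chosen only after seeing the data were genes with a mean of at least 50 CPM, counts scaled to effective tags, the separated protrusion and open neural tube 13 both left out, and an estimated correlation without the separated protrusion. The 67 genes kept their direction in every alternative in which they were tested. The count of changed genes (67, 31 higher and 36 lower) was 103 with upper-quartile factors (62 lower), 98 with no scaling factor (50 higher), 157 with at least 20 CPM in 4 libraries (53 higher, 104 lower), 795 with DESeq2 (408 higher, 387 lower), 370 with limma-voom (221 higher, 149 lower), 189 with sample weights (103 higher, 86 lower), 36 with protrusions 1 and 2 summed (14 lower), 214 at a mean of at least 50 CPM (106 higher, 108 lower), 297 when scaled to effective tags (132 higher, 165 lower) and 211 without both libraries (115 higher, 96 lower). Leaving out each library in turn gave 1 to 172 changed genes, 1 to 87 higher and 0 to 85 lower, with 1 to 64 of the 67 among them. Of the 67 genes, 44 were called with sample weights, 61 with limma-voom and 67 with DESeq2. The 7 changed lists became 4 with at least 20 CPM in 4 libraries, at a mean of at least 50 CPM and when scaled to effective tags, where fewer lists could be tested. They became 12 without both libraries, 0 with an estimated correlation, 2 with it without the separated protrusion, and 6 to 9 when each library was left out. The neural tube closure list, towards lower in camera, was called towards higher by fry (adjusted p = 0.0251, median 0.14), which does not compare a list with other genes.

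For library similarity, the excess distance between groups (1.37) was 0.69 with at least 20 CPM in 4 libraries, 1.46 with protrusions 1 and 2 summed and 0.56 when scaled to effective tags (exact permutation p = 0.0571 each), and 0.80 to 2.06 when each library was left out. Without both libraries it was 2.66 (exact p = 0.100, the smallest that 10 splits allow). The spread within each group (difference −0.43) was −0.046 without the low-count filter, −0.10 at a mean of at least 50 CPM, −0.41 without both libraries, and −0.52 to −0.25 when each library was left out. For separated against attached protrusions, the streak list (−1.10) ranged from −2.35 to −0.86 when each library was left out, and has no value without protrusion 1, with protrusions 1 and 2 summed or without both libraries. Apart from fewer genes or libraries where an alternative removes them, the cause was not tested. Among genes taken by the fixed rule, 1695 values under the alternatives kept their side of the threshold, 211 lost the call and 85 gained it. Among lists 850 kept it, 29 lost it and 29 gained it. The values that kept their side include those of genes and lists not called in the main comparison, which have no call to lose. All losses fall on the called genes and lists, and are a larger share of the values of these. No paired analysis was possible because the labels tie no protrusion to an open neural tube by embryo, litter or batch. Depth by itself limited genes below 0.529 CPM in the shallowest library. Fewer captured tags in the open neural tube libraries could limit genes at higher levels too, but lower transcription there would also give zeros. Thinning to the smallest total gave 77 changed genes.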

Other observations

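The genes named in this part, the tests of list means over the splits, and the combination of an estimated correlation with leaving out the separated protrusion were chosen only after the data were seen. Without the separated protrusion, 87 genes were higher and 85 lower in the 3 attached protrusions than in the 4 open neural tubes (edgeR, adjusted p under the threshold of 0.05). Camera called 9 of 38 lists in this comparison, among them those of the primitive streak and of FGF/ERK targets as higher (median 6.24 and 2.76, adjusted p = 1.18e-11 and 2.51e-06), and these were the 2 lists still called with an estimated correlation (adjusted p = 0.0474 each). Mixl1, a homeobox gene of the primitive streak, stood at 29.1, 57.7 and 11.2 CPM in the attached protrusions, at 0.65 CPM in the separated one, and at 0 in all open neural tubes, as was Polr2a, which every cell uses, so a 0 there does not show absence. Rarg, a retinoic acid receptor of the caudal embryo, stood at 41.8 to 48.2 CPM in the attached protrusions and at most at 0.16 CPM in the other libraries (edgeR adjusted p = 0.00406). T was higher by 6.54 (adjusted p = 0.0396), and the signals Fgf4, Fgf17 and Wnt8a passed as well (adjusted p = 0.0309, 0.0489 and 0.0328). Genes of general function passed too, among them Eif5a and Vars (edgeR adjusted p = 0.0392 and 0.0374). In the separated protrusion these stood at 94.1 and 27.0 CPM, below the open neural tubes at 224 to 713 and 114 to 284 CPM. Of 80 higher genes evaluated, 18 lay below all open neural tubes there. Whether this contrast is partly technical was not tested.

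Among the lower genes, Zic1, a transcription factor of the dorsal neural plate, changed by −7.66 (edgeR adjusted p = 0.0390), Nr2f1, a nuclear receptor of the developing nervous system, by −7.01 (adjusted p = 0.0136), and Sox1, an early neural plate gene, by −3.78 (adjusted p = 0.0350). Fgfr2 and Fgfr3, FGF receptors of the neural tube, changed by −3.73 and −4.13 (adjusted p = 0.0177 and 0.0338), and Sfrp1 by −3.32 (adjusted p = 0.0252). The endothelial gene Sox7 changed by −7.34 and the neural crest gene Ednrb by −6.29 (adjusted p = 0.0177 and 0.0370). Camera called the dorsoventral patterning, neural progenitor and endothelial lists lower (median −3.69, −0.98 and −3.20, adjusted p = 0.00270, 0.0203 and 0.00109), with adjusted p = 0.540, 0.666 and 0.493 with an estimated correlation. The neural crest and neuronal differentiation lists were not called (median −1.24 and 0.54, adjusted p = 0.126 and 0.591). In the separated protrusion Sox1 stood at 108 CPM, against 4.01 to 6.85 CPM in the attached protrusions and 15.3 to 99.6 CPM in open neural tube.

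Over the 35 splits, the mean log2 CPM of the streak list differed by 4.50, of FGF targets by 3.29, of Wnt targets by 2.24, of posterior Hox genes by 6.10 and of the paraxial list by 2.21 between protrusions and open neural tube (exact permutation p = 0.0286 each, the smallest possible, 0.0987 adjusted over the 38 lists). The same p was found for 6 lists that camera did not call, Notch (1.77), pluripotency (2.20), neuronal differentiation (1.31), p53 (1.00), neural tube closure (0.43) and oxidative stress (0.34, although camera ran towards lower), so this test does not set the called lists apart. The endothelial list differed by −1.65 (exact p = 0.200) and oxidative phosphorylation by −0.13 (exact p = 0.229). Egr2, a hindbrain gene, was at 33.1 CPM in open neural tube 14 and 30.3 CPM in the separated protrusion and at 0 in the other 6 libraries. Xist was at 301 CPM in open neural tube 10 and 400 CPM in protrusion 3, the libraries lowest for Uty and Ddx3y, and at most at 6.31 CPM in the others. Uty stood at 0.882 and 0.262 CPM in these libraries and at 37.1 to 101 CPM in the others. This is the pattern of female tissue in open neural tube 10 and protrusion 3 and of male tissue in the others. These libraries thus do not share an embryo with the rest of their group.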
